A study of Mus musculus with 48 samples.

How the data were processed

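Short RNA was sequenced from 48 ganglia samples of Balb/c mice, with 24 libraries from the superior cervical ganglion (SCG), a sympathetic ganglion, and 24 from the trigeminal ganglion (TG), the sensory ganglion of the face. Per the labels, 48 mice aged 2.5 months, 24 male and 24 female, received an intraperitoneal injection of 0.2 mL saline alone or with lipopolysaccharide (LPS) of Escherichia coli at 2.5 mg/kg. LPS is a bacterial cell wall component that sets off systemic inflammation. The 2 ganglia of each kind were taken from each mouse at 4 h, 24 h or 7 d, and 48 of the 96 RNA samples were sequenced. The mean RNA integrity number of the sequenced samples was 8.3 (range 6.4 to 9.3), and each library was made from 140 ng of total RNA with a ligation-based small RNA kit. Mean RNA yield was 193 ng/uL for TG and 64 ng/uL for SCG.

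The deposited values are counts: the authors gave 1 table of whole-number counts per mature microRNA (miRNA) and 1 of whole-number counts per tRNA fragment (tRF), without normalisation. The authors' processing notes name FastQC 0.11.9 and the mouse genome build GRCm39, and the column names of the tRF table show that reads had passed through flexbar. The aligner and the counting program are not given in the sources used here. A further table, text annotation only, gave each tRF its fragment type and its locations in tRNA space. Those locations are human: of 13007 annotated tRFs, 346 had a location on chromosome 20, 21 or 22, and 3705 had a location on a chromosome the mouse lacks or past the last mouse gene of that chromosome. None of the 55 tRFs with a mitochondrial location was found without mismatch in the 22 mouse mitochondrial tRNA sequences, and these tRFs held 136 of 12563678 tRF counts. The fragment type and parent tRNA of a tRF are therefore printed as the deposited annotation gives them, and no genome position is given for a tRF. A tRF that occurs in mouse but not in human tRNAs would be missing from the table, which was not tested here.

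Libraries were grouped by ganglion, treatment and time from the labels, giving 12 groups of 4 libraries, with 2 female and 2 male libraries in each. The column names of 2 libraries, from SCG and from TG, spell LPS without its first letter. The label of the SCG library spells it in full and gave its treatment. The label of the TG library also lacks that letter, and its treatment was taken from the sample description. The replicates of a group came from different mice. The labels do not say which SCG and TG libraries share a mouse, and replicate numbers follow the order of the labels, so no animal term was used.

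Total counts per library are the depth behind each value. For miRNAs they ran from 1774047 to 5592766 (median 3536934), and for tRFs from 61218 to 1511191 (median 204269). Differences between libraries were tested against the spread between replicates, which was larger than counting error. In the 72 pairs of replicates the squared differences averaged at least 23.9 times the counting variance (chi-square per degree of freedom of the miRNA counts). Group values are given as mean ± SD in CPM, counts scaled to a common library total after trimmed mean of M-values (TMM) scaling, and log2 fold changes as estimate ± SE.

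Each miRNA and tRF was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, expression filter by group with a minimum count of 10, robust dispersion). The 24 libraries of each ganglion were fitted together with 6 groups of time and treatment and an additive sex term. P values were adjusted by Benjamini-Hochberg within each comparison, and features with adjusted p under 0.05 were called. TG was compared with SCG over the 24 saline libraries with terms for time and sex. Interaction terms tested whether the LPS effect differed between ganglia (all 48 libraries in 1 fit), between times, and between sexes. Tests are two-sided.

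Before the data were examined, 20 lists of miRNAs (194 names) were fixed: NF-kB and LPS-induced, leukocyte, erythroid, neuron, miR-183 cluster of sensory neurons, activity-induced miR-132 and its cluster partner, glia, endothelium, muscle, epithelium and pituitary, mesenchyme and smooth muscle, cartilage, liver, hypoxia, p53 and stress, Hox cluster, Dlk1-Dio3 cluster, let-7 family, miR-17-92 and paralog clusters, and X-linked. Some miRNAs stand on more than 1 list. The lists and the tRF families (fragment type, parent amino acid, parent anticodon, origin; at least 10 tested members) were tested with camera of limma 3.58.1 with an estimated inter-gene correlation. The hypoxia list had fewer than 2 tested members and was not tested as a list. A preset correlation of 0.01 and fry were run as alternatives. Shares of tRF fragment types were compared between 4 LPS and 4 saline libraries with an exact permutation test (70 assignments, smallest p 0.0286). Between ganglia a permutation test with 100000 permutations was used, which was added after the data were seen.

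The miRNAs named were chosen by a rule, also fixed before the data were examined. For each LPS comparison it takes up to 12 called miRNAs and 6 called tRFs per direction with the smallest adjusted p, every called list member, and 14 miRNAs whatever their values. For TG against SCG it takes up to 12 miRNAs and 6 tRFs per direction by fold change among those called with a mean of at least 100 CPM in 1 ganglion. For sex and the interactions it takes up to 6 per direction.

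The alternatives fixed in advance were DESeq2 size factors in place of TMM, no low-count filter, the test of DESeq2 1.42.0, no sex term, a fit to only the 8 libraries of a ganglion and time, library size alone as the scale between ganglia, other sets of tRFs behind the class shares, and leaving out each library in turn. Alternatives chosen after the data were seen left out SCG 7 d LPS replicate 2, TG 7 d saline replicates 1, 2 and 4, or both, left out each saline library in turn between the ganglia, or compared the 7 d LPS libraries with the 8 saline libraries of 4 h and 24 h.

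The pipeline was tested on simulated counts with 200 changed features, the changes being put into the 24 h LPS group. Means and dispersions were those of all 24 libraries of a ganglion, in SCG with 7 d LPS replicate 2 included. With so many changed features the adjusted threshold is looser than with few, so a few changes may be recovered less often. With 4-fold changes it recovered 87.9% of miRNAs in SCG and 95.5% in TG, and 50% of tRFs in SCG and 89.4% in TG. At 2-fold these shares were 46.3%, 68.7%, 8.96% and 22.4%, and at 1.5-fold 7.46%, 50.7%, 1.49% and 2.99%. Simulations without changes gave 0 calls.

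Precursor positions are from a GENCODE annotation on build GRCm38, not the build the authors name. The sequence reads were not analysed here.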

Results

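MiRNAs and tRFs were counted in 48 ganglia libraries from mice given saline or LPS, with 4 libraries (2 female, 2 male) for each of SCG and TG at 4 h, 24 h and 7 d. Total miRNA counts ran from 1774047 to 5592766 per library, with a median of 2916062 in SCG and 4101287 in TG. Total tRF counts ran from 61218 to 1511191. Between 742 and 916 miRNAs were detected per library (median 839), and between 1371 and 2881 tRFs (median 1990). The 10 most abundant miRNAs held 54.5% to 62.0% of the miRNA counts of a library, and the 10 most abundant tRFs 69.6% to 90.4% of the tRF counts. The most abundant miRNA was miR-99a-5p, at 96914 ± 15012 CPM in SCG and 129280 ± 11093 CPM in TG (mean ± SD, n = 24 each). Replicate pairs had a correlation across miRNAs (log2 CPM; miRNAs are not independent replicates) between 0.937 and 0.992 in 69 of 72 pairs. In the other 3 pairs, all with SCG 7 d LPS replicate 2, it was 0.736 to 0.778. That library also differed in marker miRNAs, as given with the 7 d values.

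The first question was which small RNAs change in a sympathetic ganglion in the hours after LPS. At 4 h in SCG no miRNA passed the test, but miR-155-5p and miR-21a-5p, which are induced by inflammatory signalling in immune cells, lay above every saline library in 4 of 4 LPS libraries. The level of miR-155-5p was 23.5 ± 5.15 CPM after saline and 77.8 ± 27.0 CPM after LPS (mean ± SD, n = 4), a log2 fold change of 1.73 ± 0.37 (SE; adjusted p = 0.0702). That of miR-21a-5p was 6103 ± 1343 CPM and 12352 ± 776 CPM, a log2 fold change of 1.02 ± 0.31 (adjusted p = 0.857). The NF-kB and LPS-induced list passed as a list, with 2 of its 16 tested members higher when adjusted over the list alone and 0 over all miRNAs (adjusted p = 0.0474 with an estimated correlation; median log2 fold change 0.12). Its member miR-146a-5p, a brake on NF-kB signalling, had a log2 fold change of 0.21 ± 0.30 (adjusted p = 0.998). In SCG 4 h saline replicate 1 the muscle miR-1a-3p was 92427 CPM and the keratinocyte miR-203-3p 10553 CPM, against medians of 541 and 306 CPM over 20 other SCG libraries (highest 20992 CPM, in SCG 4 h saline replicate 2, and 1103 CPM). The muscle list had a median log2 fold change of -2.35, epithelium and pituitary one of -2.45 and mesenchyme and smooth muscle one of 0.71, with 0 members called (adjusted p = 0.616 each with an estimated correlation; 0.145, 0.184 and 2.75e-05 with the preset correlation). Without SCG 7 d LPS replicate 2, 1 muscle and 1 epithelium and pituitary member fell when adjusted over the list alone. The blood and leukocyte miRNAs miR-451a, miR-223-3p and miR-142a-3p had log2 fold changes of 0.83 ± 0.49, 0.25 ± 0.48 and 0.14 ± 0.82. Of 506 miRNAs tested with edgeR, 0 had adjusted p under 0.05, 13 had unadjusted p under 0.05, and DESeq2 called 1. Without SCG 7 d LPS replicate 2, which widened the spread of the joint fit, 3 miRNAs were called at 4 h: miR-155-5p (log2 fold change 1.72 ± 0.27, adjusted p = 0.000946), miR-155-3p (4.33 ± 0.58, 0.000204; named after its values were seen) and miR-21a-5p (1.02 ± 0.22, 0.0279). Leaving out SCG 4 h LPS replicate 4 gave 2 calls, and leaving out any 1 of the 4 saline libraries of 4 h gave 1.

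At 24 h in SCG, miR-155-5p and miR-21a-5p rose. The level of miR-155-5p went from 16.2 ± 2.88 CPM after saline to 134.6 ± 40.9 CPM after LPS (mean ± SD, n = 4), an 8.31-fold rise (log2 3.05 ± 0.39, adjusted p = 7.93e-05). That of miR-21a-5p went from 6552 ± 2677 CPM to 28705 ± 6297 CPM, a 4.39-fold rise (log2 2.13 ± 0.32, adjusted p = 0.000419). Both lay above every saline library in 4 of 4 LPS libraries, and they were the 2 miRNAs called of 506 (24 at unadjusted p under 0.05). The precursor of miR-155 lies in an exon of the noncoding Mir155hg (chromosome 16, 84714140 to 84714204), and that of miR-21a overlaps an exon of Vmp1 (chromosome 11, 86584067 to 86584158). MiR-146a-5p was at 2014 ± 196 CPM and 4939 ± 2305 CPM (log2 1.28 ± 0.30, adjusted p = 0.0783), and miR-146b-5p had a log2 fold change of 0.69 ± 0.30. The NF-kB and LPS-induced list passed as a list, with 2 of 16 members up and 3 when adjusted over the list alone (adjusted p = 0.00347 with an estimated correlation; median 0.10, mean 0.54). Members of the leukocyte list had a median log2 fold change of 0.81, with 0 of 9 called and 1 up when adjusted over the list alone (adjusted p = 0.226 with an estimated correlation). They included the granulocyte miR-223-3p at 1.28 ± 0.48 and the pan-leukocyte miR-142a-3p at 1.12 ± 0.83.

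Without SCG 7 d LPS replicate 2, 6 miRNAs were called at 24 h: miR-155-5p (log2 3.08), miR-21a-5p (2.15), miR-223-5p (1.34), miR-146a-5p (1.31), miR-142a-3p (1.09) and miR-222-3p (0.81); miR-223-5p and miR-222-3p were named after their values were seen. In that fit the leukocyte list passed as a list, with 2 of 9 members up and 5 when adjusted over the list alone (adjusted p = 0.00617 with an estimated correlation). The 3 members of the miR-183 cluster, made by sensory neurons, were lower after LPS when adjusted over the list alone, and 0 were called over all miRNAs (median log2 -2.93; adjusted p = 0.0792 with an estimated correlation). Their saline mean was carried by 1 library: miR-183-5p was 13472 CPM in SCG 24 h saline replicate 1, against a group mean of 3959 ± 6348 CPM and 304 ± 197 CPM after LPS. Without that library the log2 fold change of miR-183-5p moved from -3.11 to -1.30. With DESeq2 7 miRNAs were called (5 up, 2 down), and with only the 8 libraries of this time 5.

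At 7 d in SCG, 3 miRNAs of the NF-kB and LPS-induced list rose, in 4 of 4 LPS libraries above every saline library. MiR-146a-5p went from 1634 ± 640 CPM to 7551 ± 2299 CPM (4.65-fold; log2 2.22 ± 0.31, adjusted p = 0.000421). MiR-155-5p went from 19.5 ± 3.25 CPM to 96.3 ± 63.7 CPM (4.86-fold; log2 2.28 ± 0.38, adjusted p = 0.00131), and miR-21a-5p from 5390.3 ± 395 CPM to 20107 ± 12028 CPM (3.71-fold; log2 1.89 ± 0.31, adjusted p = 0.00131). The precursor of miR-146a is intergenic (chromosome 11, 43374397 to 43374461). The list as a whole did not pass (adjusted p = 0.533 with an estimated correlation), with 4 of 16 members up when adjusted over the list alone. Its median log2 fold change was -0.14, while its mean was 0.35 and the test pointed up. MiR-146b-5p had a log2 fold change of 1.08 (adjusted p = 0.113).

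Several other lists moved at 7 d in SCG with 1 library. In SCG 7 d LPS replicate 2, miR-142a-3p was 3756 CPM, against a saline mean of 66.5 ± 10.5 CPM, and the neuronal miR-124-3p was 4.09 CPM, against 162 ± 44.4 CPM (n = 4). Over all 4 LPS libraries the median log2 fold change was 1.56 for the leukocyte list, 1.86 for the miR-17-92 and paralog clusters, which are active in dividing cells, and 5.46 for epithelium and pituitary. It was 3.84 for muscle, 1.20 for mesenchyme and smooth muscle, -0.61 for neurons and -0.51 for the Dlk1-Dio3 cluster. None of these lists had a member called over all miRNAs or passed as a list (adjusted p = 0.600 for muscle and 0.533 for the others, with an estimated correlation). Adjusted over the list alone, 15 of 15 members of the miR-17-92 list were up, as were 3 of 4 of epithelium and pituitary and 5 of 9 leukocyte miRNAs, with 1 leukocyte miRNA down. Without that library these list counts were 0, 0, 1 up and 2 down, and the median of the leukocyte list was 0.12.

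The 3 calls of 7 d in SCG held without SCG 7 d LPS replicate 2, with log2 fold changes of 2.12 for miR-146a-5p, 1.74 for miR-155-5p and 1.40 for miR-21a-5p (adjusted p = 0.00145 each). The number called depended on the libraries and the test: 3 of 506 with edgeR (103 at unadjusted p under 0.05), 40 with DESeq2, 32, 29 and 13 when SCG 7 d LPS replicate 1, 3 or 4 was left out, and 0 with only the 8 libraries of this time. Leaving out replicate 1 or 3 also brought miR-146b-5p, miR-223-3p and miR-142a-3p past the test (smallest adjusted p = 0.0226, 0.0419 and 0.0188), and leaving out replicate 4 miR-142a-3p. These fits keep replicate 2, where miR-142a-3p was 3756 CPM, against 80.6 to 94.0 CPM in the rest of its group. Without replicate 2 the log2 fold changes of these miRNAs were 0.69, 0.77 and 0.46 (edgeR, adjusted p = 0.458, 0.503 and 0.508).

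**Figure D1:**
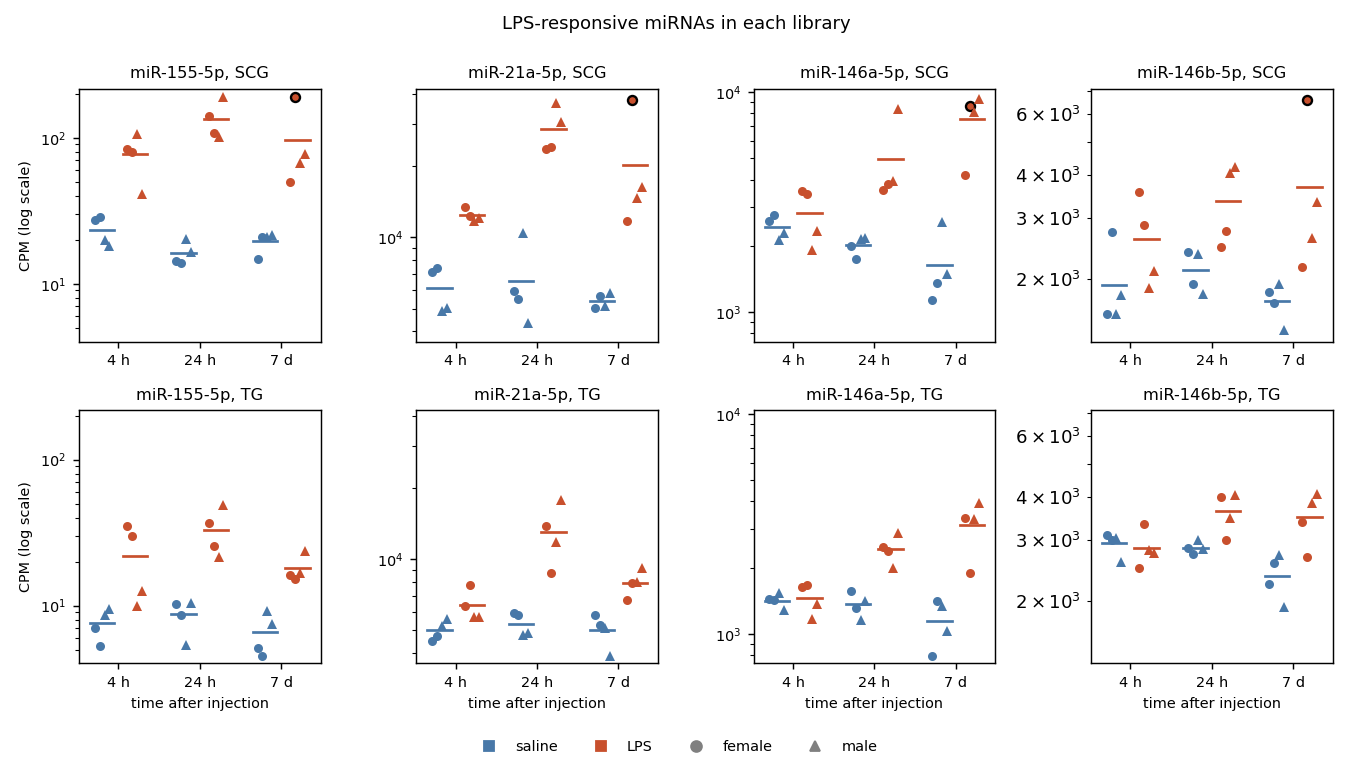
MiR-155-5p, miR-21a-5p, miR-146a-5p and miR-146b-5p in SCG and TG after saline or LPS. Each point is 1 library in CPM on a log axis (circles female, triangles male), bars are group means (n = 4), and SCG 7 d LPS replicate 2 has a black outline; at 24 h miR-155-5p lay between 13.9 and 20.1 CPM in the 4 saline libraries of SCG and between 100.6 and 189.9 CPM in the 4 LPS libraries.

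The same question was asked of a sensory ganglion. At 4 h in TG, miR-155-5p was 7.60 ± 1.88 CPM after saline and 21.99 ± 12.6 CPM after LPS (mean ± SD, n = 4; 2.83-fold; SE 0.38 on the log2 scale; adjusted p = 0.123). The lowest LPS library, at 9.94 CPM, lay just above the highest saline library, at 9.55 CPM. The log2 fold change was 2.41 ± 0.38 in females and 0.31 ± 0.36 in males (SE, n = 2), and the test over all 3 times did not call a difference between the sexes (adjusted p = 0.339). MiR-21a-5p had a log2 fold change of 0.34 ± 0.17, also with 4 of 4 libraries above saline, and miR-146a-5p one of 0.04 ± 0.19. The erythroid list had a median log2 fold change of -0.81, with 2 of its 7 members down when adjusted over the list alone and 0 called (adjusted p = 0.11 with an estimated correlation). Its most abundant member, the red cell miR-451a, was 1007 ± 269 CPM after saline and 552 ± 250 CPM after LPS (log2 -1.11 ± 0.58). The NF-kB and LPS-induced list had 1 of 17 members up when adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). Of 538 miRNAs tested with edgeR 0 were called, 15 had unadjusted p under 0.05, and DESeq2 called 2. Leaving out TG 4 h LPS replicate 3 gave 1 call, miR-155-5p (log2 1.79, adjusted p = 0.0383).

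At 24 h in TG, as in SCG, miR-21a-5p and miR-155-5p rose. MiR-21a-5p went from 5331 ± 580.5 CPM to 12972 ± 3756 CPM (2.43-fold; log2 1.28 ± 0.17, adjusted p = 0.000142), and miR-155-5p from 8.69 ± 2.35 CPM to 33.2 ± 12.3 CPM (3.81-fold; log2 1.93 ± 0.36, adjusted p = 0.00819). Both were above every saline library in 4 of 4 LPS libraries (n = 4 per group). MiR-146a-5p was 1362 ± 172 CPM and 2429.5 ± 354.1 CPM (log2 0.83 ± 0.20, adjusted p = 0.0665), also above saline in 4 of 4, and miR-146b-5p had a log2 fold change of 0.35 ± 0.13. The NF-kB and LPS-induced list had 2 of 17 members up, 3 when adjusted over the list alone, and adjusted p = 0.0713 with an estimated correlation (median 0.20, mean 0.40). The leukocyte list had a median of -0.00 and the neuron list one of -0.05 (adjusted p = 0.998 each with an estimated correlation). The 2 called miRNAs were of 538 tested (23 at unadjusted p under 0.05). MiR-155-5p was no longer called without TG 24 h saline replicate 3 (log2 1.74, adjusted p = 0.0660) or TG 24 h LPS replicate 4 (1.65, 0.0597). With only the 8 libraries of this time neither miR-21a-5p (adjusted p = 0.203) nor miR-155-5p (0.102) was called, and the 1 call was miR-146a-5p (0.0487).

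At 7 d in TG, 10 miRNAs rose and 23 fell. The 4 members of the NF-kB and LPS-induced list that rose were miR-146a-5p, miR-155-5p, miR-21a-5p and miR-146b-5p. MiR-146a-5p went from 1144 ± 285 CPM to 3127 ± 868 CPM (mean ± SD, n = 4; 2.73-fold; log2 1.45 ± 0.20, adjusted p = 0.000239), and miR-155-5p from 6.57 ± 2.14 CPM to 18.0 ± 3.93 CPM (2.77-fold; log2 1.47 ± 0.37, adjusted p = 0.0231). MiR-21a-5p rose 1.58-fold (log2 0.66 ± 0.17, adjusted p = 0.0234) and miR-146b-5p 1.47-fold (log2 0.56 ± 0.13, adjusted p = 0.0123). On the same list miR-212-5p fell (log2 -1.24 ± 0.34, adjusted p = 0.0338), 4 members were up and 3 down when adjusted over the list alone, and the list did not pass (adjusted p = 0.932 with an estimated correlation; median -0.04 and mean -0.09, with the test pointing up). The hypoxia-induced miR-210-3p rose from 23.9 ± 5.61 CPM to 36.5 ± 1.74 CPM (1.52-fold; log2 0.61 ± 0.14, adjusted p = 0.0119). The other miRNAs that rose were miR-24-3p, let-7b-5p, miR-24-2-5p, the erythroid miR-486b-3p, and miR-363-3p, with log2 fold changes between 0.24 and 0.73 (adjusted p between 0.0231 and 0.0312). Against the saline libraries of 4 h and 24 h miR-486b-3p was lower after LPS (log2 -0.14), a reversed direction.

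Of the miRNAs that fell at 7 d in TG, 4 stand on the neuron list. MiR-9-5p fell from 18714 ± 3940 CPM to 11412 ± 500.3 CPM (log2 -0.71 ± 0.12, adjusted p = 0.00115), miR-9-3p from 1625 ± 684 CPM to 633 ± 40.6 CPM (log2 -1.34 ± 0.23, adjusted p = 0.00149), miR-124-3p from 507 ± 172 CPM to 281 ± 32.1 CPM (log2 -0.85 ± 0.19, adjusted p = 0.0106) and miR-128-3p from 25965 ± 7581 CPM to 16238 ± 799 CPM (log2 -0.67 ± 0.17, adjusted p = 0.0231). These are 4 of 13 tested members, with 8 down when adjusted over the list alone, but the list did not pass (adjusted p = 0.849 with an estimated correlation; median -0.48). The steepest falls were those of miR-135a-5p (89.5 ± 50.5 CPM to 8.18 ± 5.12 CPM; log2 -3.40 ± 0.68, adjusted p = 0.00873), miR-135a-2-3p (-3.48 ± 0.88, 0.0231) and miR-708-3p (189 ± 81.1 CPM to 55.0 ± 15.2 CPM; -1.77 ± 0.29, 0.0013). Others by rank were miR-342-3p (-0.46), miR-129-2-3p (-1.39), miR-344-3p (-1.23), miR-129-1-3p (-0.81) and miR-598-3p (-0.55). The neuron list holds miR-129, but names were matched exactly, so miR-129-2-3p and miR-129-1-3p are not counted among its members. The fallen list members also included miR-10a-5p of the Hox cluster (-1.46), and miR-369-5p (-0.74) and miR-495-3p (-0.58) of the Dlk1-Dio3 cluster.

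These falls went with the saline libraries. MiR-9-5p was 12870 CPM in TG 7 d saline replicate 3, while the group mean of the 4 saline libraries was 18714 CPM, and miR-128-3p was 14690.3 CPM in that library against a mean of 25965 CPM. The other 3 saline libraries stood apart from it in the same direction for miR-124-3p, which was 249.8 CPM in replicate 3 and up to 606 CPM in the others. Against the 8 saline libraries of 4 h and 24 h, 1 miRNA was called at 7 d, miR-146a-5p (log2 1.17, adjusted p = 0.000321), and without TG 7 d saline replicates 1, 2 and 4, which leaves 1 saline library assumed to vary like the other groups, 0 were called by edgeR and the neuron list had a median of -0.01 (adjusted p = 0.993 with an estimated correlation). MiR-146a-5p then had a log2 fold change of 1.21 (adjusted p = 0.418), miR-155-5p 0.90 and miR-21a-5p 0.65.

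At 7 d in TG the miR-183 cluster had 3 of 6 members up when adjusted over the list alone and 0 called, with miR-183-5p at 33855 ± 4946 CPM and 42867 ± 3795 CPM (n = 4; log2 0.34 ± 0.11, adjusted p = 0.0685). The activity-induced list of miR-132 and miR-212 had a median log2 fold change of -1.09, with 1 of 6 members down and 3 when adjusted over the list alone, among them miR-132-3p at -1.40 ± 0.44. Both results depend on the saline libraries. Without TG 7 d saline replicates 1, 2 and 4, which leaves 1 saline library of 7 d, miR-132-3p had a log2 fold change of 0.62. Those of miR-183-5p, miR-182-5p and miR-96-5p were then 0.08, 0.04 and 0.02. When adjusted over the list alone the let-7 family had 4 of 14 members up, the erythroid list 2 of 7, the Hox cluster 2 up and 1 down of 3, and the glia list 1 of 3 down. These lists did not pass (adjusted p between 0.849 and 0.932 with an estimated correlation), and for the Hox cluster and glia the median (0.27 and 0.17) and the mean (-0.26 and -0.76) differed in sign, with the test pointing up. The total of 33 called of 538 (124 at unadjusted p under 0.05) became 88 without TG 7 d saline replicate 3, 19 without saline replicate 2, 18 without LPS replicate 4, 54 with DESeq2 and 1, miR-155-5p, with only the 8 libraries of this time. Of the named miRNAs called, miR-146a-5p, miR-146b-5p, miR-210-3p, miR-9-5p, miR-9-3p, miR-708-3p, miR-342-3p, miR-135a-5p, miR-129-2-3p, miR-129-1-3p, miR-344-3p and miR-124-3p passed whichever of the 8 libraries was left out, and the others did not: miR-155-5p reached adjusted p = 0.0827 without LPS replicate 4, 0.0807 without saline replicate 2 and 0.0725 without saline replicate 1, and miR-21a-5p 0.0794 without saline replicate 4 and 0.0755 without LPS replicate 4.

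**Figure D2:**
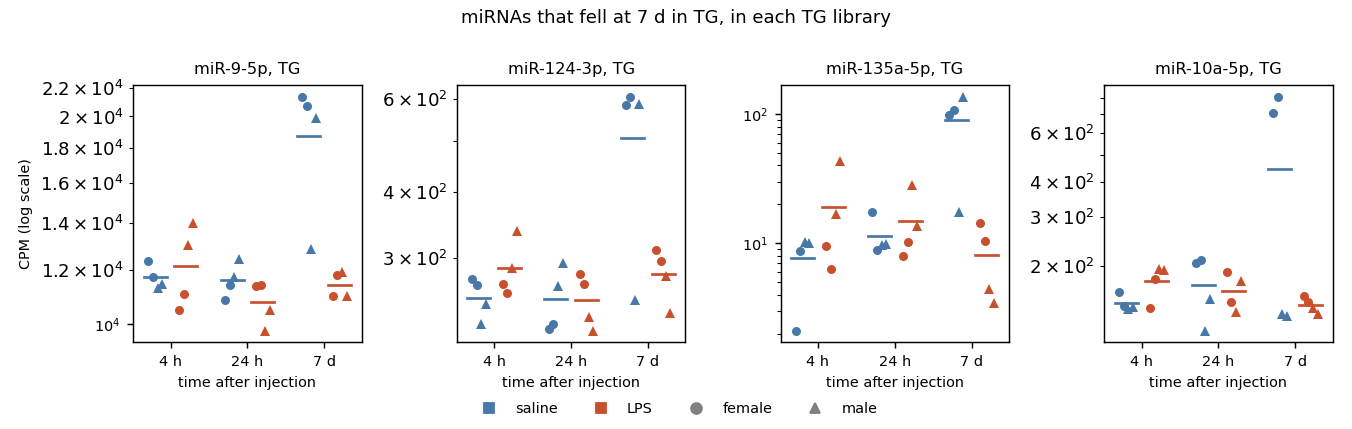
MiRNAs that fell in TG at 7 d after LPS, in the TG saline and LPS libraries of all times. Each point is 1 library in CPM on a log axis (circles female, triangles male) and bars are group means (n = 4); for miR-9-5p the 4 LPS libraries of 7 d lay between 10978.9 and 11906.1 CPM and 7 d saline replicate 3 at 12870 CPM.

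Whether the response to LPS differed between the ganglia was tested as an interaction. At 7 d the LPS effect was lower in TG than in SCG for miR-342-3p (log2 difference -1.19 ± 0.25, adjusted p = 0.0109) and miR-708-3p (-2.38 ± 0.51, adjusted p = 0.0109), from introns of Evl (chromosome 12, 108658620 to 108658718) and Tenm4 (chromosome 7, 96249424 to 96249532). For miR-155-5p, miR-21a-5p and miR-146a-5p no difference between ganglia was called at any time. Of 577 miRNAs edgeR called 0 at 4 h, 0 at 24 h and 2 at 7 d (20, 20 and 134 at unadjusted p under 0.05), and DESeq2 called 0, 3 and 65. The 2 calls ended without TG 7 d saline replicates 1, 2 and 4 (0 called). They ended without SCG 7 d saline replicate 1 or 2 or TG 7 d LPS replicate 3 or 4 (0 called each), 1 was left without TG 7 d LPS replicate 2, 62, 62, 48 and 18 were called without SCG 7 d LPS replicate 1, 3, 4 or 2, 7 and 23 without SCG 7 d saline replicate 3 or 4, and 25 and 6 without TG 7 d saline replicate 3 or 4. At 24 h 3 were called without SCG 24 h saline replicate 2, and 1 without SCG 24 h saline replicate 4, TG 24 h saline replicate 3 or TG 24 h LPS replicate 2.

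The LPS effect differed between the 3 times in TG for 8 miRNAs: miR-146a-5p, miR-708-3p, miR-135a-5p, miR-9-5p, miR-9-3p and the erythroid miR-486a-3p and miR-486b-3p (adjusted p = 0.0244 each), and miR-342-3p (adjusted p = 0.0415). For miR-146a-5p the log2 fold change was 0.04 at 4 h, 0.83 at 24 h and 1.45 at 7 d. Without TG 7 d saline replicates 1, 2 and 4, which leaves 1 saline library of 7 d, it was 1.21 at 7 d. In SCG edgeR called 0 of 506 (21 at unadjusted p under 0.05) and DESeq2 0, with miR-146a-5p at 0.21, 1.28 and 2.22. The 8 calls became 0 without TG 7 d saline replicates 1, 2 and 4, and 0 without any 1 of TG 4 h saline replicate 1, TG 4 h LPS replicate 4, TG 7 d saline replicate 1, 2 or 4, or TG 7 d LPS replicate 3. They became 1 without TG 4 h saline replicate 2 or TG 7 d LPS replicate 1, 2 without TG 7 d LPS replicate 4, 3 without TG 4 h saline replicate 3 or TG 4 h LPS replicate 3, 4 without TG 7 d LPS replicate 2, and 34 without TG 7 d saline replicate 3.

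Female and male ganglia were compared over all groups. In SCG 5 miRNAs were lower in females: miR-7689-3p (4.46 ± 1.69 CPM in females and 11.3 ± 3.45 CPM in males, mean ± SD, n = 12; log2 -1.34 ± 0.24, adjusted p = 0.00951), miR-664-5p (41.9 ± 11.3 CPM and 68.2 ± 13.5 CPM; log2 -0.72 ± 0.14, adjusted p = 0.00951), miR-215-5p (-0.84), miR-341-5p (-1.16) and miR-3084-3p (-1.31). MiR-664 lies in an intron of Rab3gap2 (chromosome 1, 185242975 to 185243043), and miR-341 belongs to the Dlk1-Dio3 cluster, of which 1 of 75 members was called. The X-linked list had a median log2 difference of 0.09 in SCG and 0.02 in TG, with 0 of 44 and 0 of 48 members called (adjusted p = 0.818 and 0.786 with an estimated correlation). When adjusted over the list alone, 2 of 7 erythroid miRNAs were higher in female SCG, 1 of 5 muscle miRNAs was higher and 2 of 5 of the list of miR-132 and miR-212 were lower (adjusted p = 0.738 each with an estimated correlation). SCG 7 d LPS replicate 2 is a female library, and without it 32 miRNAs were called (9 higher, 23 lower). Of the Dlk1-Dio3 list, miR-323-3p, miR-329-5p, miR-337-5p, miR-341-5p, miR-409-5p, miR-412-5p, miR-667-5p and miR-770-3p were then called lower in females (log2 between -1.04 and -0.31). MiR-376a-3p of that list was called higher (log2 1.04). Apart from miR-341-5p these members were named after their values were seen. Also female are SCG 4 h saline replicate 1, with the muscle miR-1a-3p at 92427 CPM (median 541 CPM over 20 SCG libraries), and SCG 24 h and 7 d saline replicate 1, with miR-183-5p at 13472 and 4379 CPM (median 526 CPM). With DESeq2 25 were called, and 71 of 506 had unadjusted p under 0.05. In TG edgeR called 0 of 538 (24 at unadjusted p under 0.05) and DESeq2 0, with a median of 0.46 for the erythroid list.

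The LPS effect differed between sexes in TG for 1 miRNA, miR-10a-5p (adjusted p = 4.26e-05), with a log2 fold change at 7 d of -2.32 ± 0.16 in females and 0.05 ± 0.16 in males (SE, n = 2). The female saline libraries of 7 d are replicates 1 and 2, with 710 and 807 CPM, while the LPS libraries of 7 d lay between 134 and 155 CPM. Without TG 7 d saline replicates 1, 2 and 4 the log2 fold change at 7 d over both sexes was 0.0295, and no female saline library of 7 d was left to compare the sexes. Its precursor lies on chromosome 11 (96317165 to 96317274). That single call became 4 without TG 24 h saline replicate 1 or TG 24 h LPS replicate 3, 8 without TG 7 d saline replicate 4, 19 without TG 7 d saline replicate 3, and 15 with DESeq2. In SCG edgeR called 0 (24 at unadjusted p under 0.05) and DESeq2 0. Without SCG 7 d LPS replicate 1 the only female LPS library of 7 d in SCG is replicate 2. That library differed in marker miRNAs, so calls without replicate 1 rest on it and show no difference between sexes.

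Sensory and sympathetic ganglia were compared without LPS, over 12 saline libraries each. The miR-183 cluster of sensory neurons was higher in TG in 5 of 5 members (5 when adjusted over the list alone; median log2 difference 4.58, adjusted p = 0.277 with an estimated correlation). MiR-183-5p was 40270 ± 6457 CPM in TG and 2175 ± 3650 CPM in SCG (mean ± SD, n = 12), a 26.5-fold difference (log2 4.73 ± 0.55, adjusted p = 1.79e-07). Without SCG 24 h saline replicate 1 the SCG mean of miR-183-5p was 1175 CPM and the difference 37.4-fold. MiR-96-5p was 34.4-fold and miR-182-5p 23.9-fold higher in TG. Among called miRNAs with a mean of at least 100 CPM in 1 ganglion, the oligodendrocyte and glial miR-219a-2-3p differed most in that direction. It was 612 ± 533 CPM and 20.8 ± 51.4 CPM (46.6-fold, log2 5.54 ± 0.76, adjusted p = 1.75e-06). On the scale of the TG libraries alone it averaged 584 CPM over the saline libraries and 451 CPM over all 24. Next came miR-216b-5p (34.8-fold), miR-96-5p, the miR-216b neighbour miR-217-5p (34.3-fold) and the p53 target miR-34a-5p (29.7-fold). Without SCG 7 d saline replicate 1 miR-219a-2-3p was 85.2-fold higher in TG, and without SCG 24 h saline replicate 1 miR-217-5p was 52.0-fold higher. MiR-504-5p was 9.65-fold and miR-383-5p 6.68-fold higher in TG. The epithelial miR-200a-3p, miR-200c-3p and miR-200b-3p were 10.6, 8.30 and 7.58-fold higher, with SDs above their means in SCG and in TG. Without SCG 4 h saline replicate 1 these were 21.3, 19.2 and 15.9-fold, and without TG 24 h saline replicate 3 they were 5.54, 4.20 and 3.52-fold, the last with adjusted p = 0.0757. Of the glia list 2 of 2 members were higher in TG (adjusted p = 0.225 with an estimated correlation), of the erythroid list 7 of 7 (0.674) and of epithelium and pituitary 3 of 4 (0.733).

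SCG was higher for the Hox cluster, the miRNAs that lie among the Hox genes of the trunk, in 4 of 4 members (median log2 difference -3.18, adjusted p = 0.0361 with an estimated correlation). MiR-10a-5p was 4259 ± 383 CPM in SCG and 266 ± 250 CPM in TG (n = 12; 19.5-fold, log2 -4.29 ± 0.28, adjusted p = 9.17e-12). Its highest TG values were those of TG 7 d saline replicates 1 and 2, which also stood apart in the 7 d comparison; without replicate 1 the TG mean was 222 CPM (20.9-fold) and without replicate 2 it was 213 CPM (21.3-fold). MiR-615-3p, from an intron of Hoxc5 (chromosome 15, 103014910 to 103015001), was 420 ± 61.5 CPM and 7.90 ± 16.5 CPM (149-fold, log2 -7.22 ± 0.77, adjusted p = 5.26e-08). That fold is the fitted value and lies above the ratio of the 2 means. The TG mean was carried by TG 7 d saline replicates 1 and 2, at 36.9 and 44.95 CPM, where the other TG saline libraries were at most 3.17 CPM; without TG 7 d saline replicate 1 or 2 the TG mean was 5.11 or 4.33 CPM and the fold 166 or 175. MiR-218-5p, a miRNA of motor and autonomic neurons, was 31912 ± 3645 CPM and 2361 ± 144 CPM (13.5-fold, log2 -3.75 ± 0.06, adjusted p = 1.37e-23). The neuroendocrine miR-7b-5p and miR-7a-5p were 9.22 and 5.29-fold higher in SCG, miR-490-3p 10.9-fold, miR-34c-5p 6.01-fold and miR-6540-5p 4.85-fold. In TG miR-7b-5p had an SD above its mean (1447 ± 1647 CPM). MiR-203-3p, a keratinocyte miRNA, was 7.66-fold higher in SCG, at 1122 ± 2800.4 CPM, with 10553 CPM in SCG 4 h saline replicate 1; without that library its mean was 314 CPM and the difference 4.79-fold. Of the Dlk1-Dio3 cluster, imprinted miRNAs that many neurons express, 56 of 67 members were lower in TG and 1 was higher (57 lower and 1 higher when adjusted over the list alone; median -0.81, adjusted p = 0.0791 with an estimated correlation), among them miR-323-3p (7.13-fold), miR-409-3p (6.32-fold) and miR-673-5p (5.23-fold).

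In the other lists, counted as members higher and lower in TG, the neuron list had 6 and 7 of 13, the NF-kB and LPS-induced list 3 and 5 of 16, the leukocyte list 2 and 2 of 8, and the let-7 family 7 and 3 of 13. The X-linked list had 6 and 13 of 40, the miR-17-92 and paralog clusters 6 and 2 of 15, mesenchyme and smooth muscle 0 and 6 of 10, muscle 2 and 0 of 6, and the list of miR-132 and miR-212 0 and 2 of 5. Cartilage had 0 and 2 of 4, liver 2 and 0 of 3, endothelium 0 and 2 of 2, and p53 and stress 1 and 2 of 3, with a median of -1.52 and a mean of 0.26. None of these passed as a list (adjusted p between 0.674 and 0.890 with an estimated correlation). In total 333 of 471 miRNAs differed, 163 higher and 170 lower in TG (344 at unadjusted p under 0.05). The test scales each ganglion to the same total, so it gives no difference in total miRNA per cell.

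**Figure D3:**
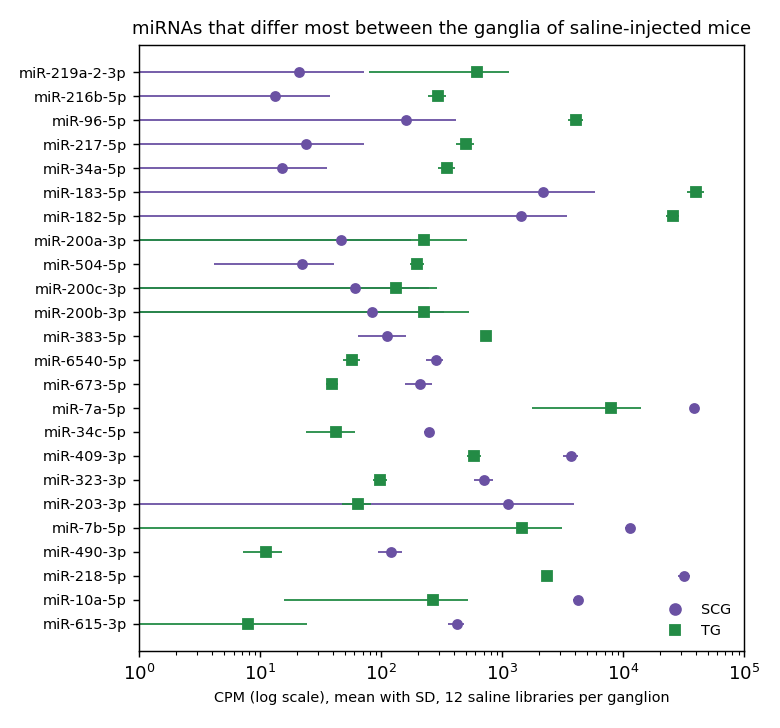
MiRNAs with the largest differences between TG and SCG over the saline libraries, among those called with a mean of at least 100 CPM in 1 ganglion. Points are means in CPM on a log axis and bars are SDs of 12 libraries per ganglion, with lower ends drawn no lower than 1 CPM; miR-183-5p was 40270 CPM in TG and 2175 CPM in SCG, and miR-10a-5p 266 CPM and 4259 CPM.

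The tRFs were compared in the same way. The most abundant, tRF-33-87R8WP9N1EWJDW, was 294539 ± 127661 CPM in SCG and 421651 ± 196968 CPM in TG (n = 24). No tRF was called after LPS: in SCG edgeR called 0 of 544 at 4 h, 24 h and 7 d (39, 26 and 27 at unadjusted p under 0.05), and in TG 0 of 559 (21, 45 and 38). DESeq2 called 0 in 5 of these 6 comparisons and 3 in TG at 7 d, and leaving out TG 7 d saline replicate 3 gave 5. With 4 libraries per group, changes of 2-fold were recovered for 8.96% of tRFs in SCG and 22.4% in TG in simulated data, so changes of that size were not detectable for most tRFs. Between females and males edgeR called 0 in SCG and in TG (50 and 53 at unadjusted p under 0.05; DESeq2 6 and 2). Between times it called 0 in both (23 and 20; DESeq2 0), and between sexes 0 (22 and 27; DESeq2 0), with 2 without SCG 4 h saline replicate 2 and 1 without TG 7 d LPS replicate 3. Between ganglia no difference in the LPS effect was called among 729 tRFs at 4 h, 24 h or 7 d (0 by edgeR; 30, 35 and 29 at unadjusted p under 0.05; DESeq2 0).

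Between the ganglia without LPS 174 of 353 tRFs differed, 99 higher and 75 lower in TG (191 at unadjusted p under 0.05). Among called tRFs with a mean of at least 100 CPM in 1 ganglion, the largest differences were those of asparagine tRNA fragments. The first, tRF-40-U1O0789NLJK1JKE1, was 776 ± 224 CPM in TG and 28.3 ± 27.0 CPM in SCG (n = 12, 27.5-fold, log2 4.78 ± 0.35, adjusted p = 4.33e-11). The others by rank were tRF-25-U1O0789NLJ (21.8-fold), tRF-38-U1O0789NLJK1JK8 (19.5-fold), tRF-23-U1O0789NDL (18.4-fold), tRF-39-U1O0789NLJK1JKEM (18.1-fold) and tRF-41-U1O0789NLJK1JKE1B (17.7-fold). The codes in the names of these asparagine fragments begin alike, so they may overlap in sequence. Fragments that share sequence are not independent, so counts of members are not counts of separate signals. SCG was higher for tRF-19-S3M830JZ (6.27-fold), tRF-31-86V8WPMN1E8Y0 (5.38-fold), tRF-31-86J8WPMN1E8Y0 (5.26-fold), tRF-30-86V8WPMN1E8Y (5.20-fold), tRF-30-RRJ89O9NF5W8 (4.88-fold) and tRF-31-87R8WP9I1EWJ0 (4.87-fold). As families, fragments of asparagine tRNA with anticodon GTT were higher in TG in 8 of 10 members (10 when adjusted over the list alone; median log2 difference 4.17, adjusted p = 0.0169 with an estimated correlation), 3'-halves in 13 of 17 with 1 lower (median 2.55, 0.0195), and fragments of aspartate tRNA with anticodon GTC in 13 of 24 with 3 lower (median 1.47, 0.0472). With library size alone as the scale, which moved the median tRF by a log2 of 0.52 (-0.11 with DESeq2 size factors), 148 tRFs were higher and 40 lower in TG, and without the low-count filter 369 differed.

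Shares of the tRF counts by fragment type were compared next. The 3'-halves, the 3' parts of tRNAs split at the anticodon, held 0.766 ± 0.262% of tRF counts in TG and 0.181 ± 0.0835% in SCG (mean ± SD, n = 12 saline libraries each), 4.24-fold more, with 12 of 12 TG libraries above every SCG library (permutation test, adjusted p = 7e-05, from the smallest p that 100000 permutations can give). The 5'-tRFs held 15.3 ± 2.40% in TG and 26.9 ± 8.91% in SCG (permutation, adjusted p = 0.00024), internal fragments 4.70 ± 1.59% and 2.54 ± 0.955% (adjusted p = 0.0022), and 5'-halves 73.7 ± 4.34% and 66.2 ± 8.74% (adjusted p = 0.021). The 3'-tRFs held 5.53 ± 2.13% and 4.13 ± 1.61% (adjusted p = 0.096), and tRFs annotated as mitochondrial did not pass (adjusted p = 0.27). Per 100 miRNA counts there were 4.11 ± 1.97 tRF counts in TG and 8.0 ± 3.16 in SCG (adjusted p = 0.0036). After LPS 42 exact permutation tests (4 against 4 libraries) gave 0 calls, but none could pass unless most of them reached the smallest p the design allows, 0.0286. It was reached by the 3'-halves in SCG at 4 h, which held 0.180% after saline and 0.0957% after LPS (adjusted p = 0.95).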

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

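The interaction tests in this part were planned, while the explanations weighed, their tests and the counts of other splits were chosen after the results were seen. In each group of 4 libraries the gap between the highest or lowest library and the next was set against the range of the group (Dixon's ratio, 95% critical value), which chance passes in about 1 in 20 groups. Of 240 combinations of group and measure, 28 passed, where chance gives about 12.

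In SCG 7 d LPS replicate 2, miR-142a-3p (3756 CPM) and miR-451a (1603 CPM) lay far above and miR-124-3p (4.09 CPM) far below the other 3 libraries of the group; 3 of 16 measures passed there, all in this library. A trigeminal sample under this label is argued against by miR-183-5p at 969 CPM, where TG libraries averaged 39878 CPM, and low depth by a total of 2938476 miRNA counts, above the median of the other SCG libraries. Tissue other than ganglion in the sample may be the cause, and this stays open: against the other 3 libraries of the group the neuron list had a median log2 ratio of -4.87 (SD 2.87 over 13 members that SCG expresses) and miR-218-5p was 337 CPM, where the median of 20 other SCG libraries was 33115 CPM. Members of the neuron list ran from -6.57 to 4.29. MiR-128-3p of that list went the other way, at 40706 CPM, where the median of those 20 libraries was 2098 CPM. Lists with a median above 1 were epithelium and pituitary (7.98), muscle (5.29), the miR-17-92 clusters (3.62), erythroid (1.82), leukocyte (1.81) and the miR-183 cluster of sensory neurons (1.81), and below -1 Dlk1-Dio3 (-3.84), glia (-3.67) and the list of miR-132 and miR-212 (-2.18), so no single cell type is singled out and no biological explanation was tested. Without this library the calls in SCG went from 0 to 3 at 4 h (edgeR; 13 at unadjusted p under 0.05, DESeq2 1) and from 2 to 6 at 24 h.

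The 23 miRNAs that fell in TG at 7 d lay below the 7 d saline libraries by a median log2 of -0.98, and saline replicate 3 stood apart from the other 3 saline libraries, low for miR-9-5p (12870 CPM), miR-124-3p (249.8 CPM), miR-129-2-3p (22.9 CPM) and miR-128-3p (14690.3 CPM) and high for miR-96-5p (4217 CPM); 7 of 38 measures passed in this group. That LPS lowered these miRNAs is argued against by their median log2 difference of -0.0683 (SD 0.17) between the 7 d LPS libraries and the 8 saline libraries of 4 h and 24 h. Central nervous tissue in the 7 d saline samples may be the cause. There the neuron list was higher than in the 8 other saline libraries by a median log2 of 0.49 (SD 0.42, 11 of 13 members). Of these 13 members 4 are also among the 23 miRNAs, as are miR-129-2-3p and miR-129-1-3p, whose names were not matched to the list. The 23 were higher by 0.89, 0.98 and 1.18 in saline replicates 1, 2 and 4 and by 0.10 in replicate 3. They were called against these same libraries, so their height there was fixed by the choice and says nothing of the cause. A difference in dissection or handling of these samples and an effect of 7 d after saline were not tested. The 10 miRNAs that rose had a median log2 of 0.08 against the 8 other saline libraries (SD 0.45, 9 of 10 above 0). Against 7 d saline their median was 0.58. As 3 of 35 splits of the 8 libraries gave at least 33 calls, chance cannot be excluded for the number of calls (33 calls, highest other split 56, with saline replicates 1, 2 and 4 and LPS replicate 1 on the same side, which points to a structure of the samples), and the 33 became 88 without saline replicate 3, 19 without saline replicate 2, 18 without LPS replicate 4 and 0 without saline replicates 1, 2 and 4 (edgeR; 124 at unadjusted p under 0.05, DESeq2 54 with all libraries).

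In SCG 24 h saline replicate 1 the sensory neuron miRNAs miR-183-5p (13472 CPM), miR-182-5p (7760.2 CPM) and miR-96-5p (937 CPM) lay far above the rest of the group, on average 28.7% of the way from SCG to TG level. Whether trigeminal tissue at that share was the cause is not settled. The miRNAs that are higher in SCG lay above the level of such a mixture by a median log2 of 0.30 (12 of 12). Their SD of 0.11 is over miRNAs of this 1 library and gives no spread between libraries. For miR-218-5p and miR-7a-5p the mixture levels, 24304 and 30151 CPM, lay within the range of 20 other SCG libraries (lowest 21627 and 28147 CPM). For miR-10a-5p the mixture level of 3158 CPM lay below that range (lowest 3694 CPM). Sensory neurons of another ganglion in the sample may be the cause: over 9 other miRNAs that are higher in TG the median was 22.03% of the way (SD 17.4), with 5 at 10% or more, while miR-219a-2-3p (2.03 CPM) and the epithelial miR-200 family were not raised. No biological explanation was tested, and without this library the log2 fold change of miR-183-5p at 24 h moved from -3.11 to -1.30. SCG 7 d saline replicate 1 was also far above its group for miR-183-5p (4379 CPM), miR-182-5p (2448.5 CPM) and miR-96-5p (318 CPM).

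The remaining libraries far from the others of their group are given as values. SCG 7 d saline replicate 1 was low for miR-155-5p (14.7 CPM) and high for miR-124-3p (228 CPM). SCG 4 h saline replicate 1 was high for miR-132-3p (57.8 CPM) and miR-122-5p (149 CPM). SCG 24 h LPS replicate 4 was high for miR-146a-5p (8389 CPM). TG 4 h saline replicate 1 was high for miR-122-5p (51.6 CPM) and replicate 3 for miR-223-3p (7.26 CPM). TG 4 h LPS replicate 1 had the lowest miRNA count of its group, 2198180. TG 24 h LPS replicate 3 was high for miR-132-3p (64.6 CPM) and miR-212-3p (6.94 CPM), and replicate 2 low for miR-122-5p (34.6 CPM). TG 7 d saline replicate 4 was high for tRF counts per 100 miRNA counts (4.98) and low for miR-142a-3p (40.6 CPM). TG 7 d LPS replicate 1 was low for miR-24-3p (17417 CPM).

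The LPS effect differed between times in TG for 8 miRNAs: miR-708-3p, miR-486b-3p, miR-486a-3p, miR-146a-5p, miR-135a-5p, miR-9-5p and miR-9-3p (adjusted p = 0.0244 each, edgeR) and miR-342-3p (adjusted p = 0.0415). Of 100 splits 3 gave as many calls (8 calls, highest other split 28). These splits drew the times anew within saline and within LPS. A difference between times in the saline libraries alone would also set the real labels apart. The count therefore does not settle chance for the LPS effect, and the split with 28 calls points to a structure of the samples. The 8 became 0 without any 1 of TG 4 h saline replicate 1, TG 4 h LPS replicate 4, TG 7 d saline replicate 1, 2 or 4, or TG 7 d LPS replicate 3 (edgeR; 70 at unadjusted p under 0.05, DESeq2 20 with all libraries). They became 1 without TG 4 h saline replicate 2 or TG 7 d LPS replicate 1, 2 and 4 without TG 7 d LPS replicate 4 or 2, 3 without TG 4 h saline replicate 3 or TG 4 h LPS replicate 3, and 34 without TG 7 d saline replicate 3. In SCG edgeR called 0 (21 at unadjusted p under 0.05, DESeq2 0), and 100 of 100 splits gave as many (highest other 1).

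The LPS effect differed between ganglia at 7 d for miR-342-3p and miR-708-3p (adjusted p = 0.0109 each, edgeR). Chance cannot be excluded for the number of calls, since 47 of 100 splits gave at least 2 calls, and the highest other split, with 75, points to a structure of the samples. The 2 calls became 0 without SCG 7 d saline replicate 1 or 2 or TG 7 d LPS replicate 3 or 4 and 1 without TG 7 d LPS replicate 2. They became 62 without SCG 7 d LPS replicate 1 or 3, 48 and 18 without its replicate 4 or 2, 7 and 23 without SCG 7 d saline replicate 3 or 4, and 25 and 6 without TG 7 d saline replicate 3 or 4 (edgeR; 134 at unadjusted p under 0.05, DESeq2 65 with all libraries). At 4 h and 24 h edgeR called 0 (20 each at unadjusted p under 0.05, DESeq2 0 and 3), and 100 of 100 splits gave as many (highest other 17 and 7). At 24 h 3 were called without SCG 24 h saline replicate 2, and 1 without SCG 24 h saline replicate 4, TG 24 h saline replicate 3 or TG 24 h LPS replicate 2.

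The LPS effect differed between sexes in TG for miR-10a-5p (adjusted p = 4.26e-05, edgeR; 2 libraries per sex and group), which became 4 calls without TG 24 h saline replicate 1 or TG 24 h LPS replicate 3, 8 without TG 7 d saline replicate 4 and 19 without TG 7 d saline replicate 3. The 2 female saline libraries of 7 d, replicates 1 and 2, are among those in doubt above, and without replicates 1, 2 and 4 the log2 fold change of miR-10a-5p at 7 d over both sexes went from -1.46 to 0.0295.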

How the results depend on the processing

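Chosen after the data were seen were the tests without SCG 7 d LPS replicate 2, without TG 7 d saline replicates 1, 2 and 4 or without both sets, leaving out each saline library in turn between the ganglia, and the comparison of 7 d LPS with the saline libraries of 4 h and 24 h; the others were planned. Counts that moved by more than 1.5 times are given as main to alternative, and for these and the reversed results the cause was not tested unless given. Where the count of the report is 0, edgeR gave it, and the report prints the count at unadjusted p under 0.05 and that of DESeq2 beside it.

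The comparison of TG with SCG held for miRNAs, with 333 calls and between 324 and 386 under DESeq2 size factors, no low-count filter, the DESeq2 test, library size alone and without TG 7 d saline replicates 1, 2 and 4 (shared with the 333: between 291 and 325). For tRFs it gave 174 calls, between 163 and 188 under these except 369 without a low-count filter (133 shared). Leaving out each saline library in turn gave between 321 and 338 miRNAs and between 168 and 188 tRFs, and of the named features 1 lost its call, miR-200b-3p without TG 24 h saline replicate 3 (log2 1.82).

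Without a low-count filter more features of few counts were tested. For miRNAs the calls in SCG went from 0 to 24 at 4 h, 2 to 15 at 24 h, 3 to 69 at 7 d, 5 to 40 for sex (3 shared), 0 to 37 between times and 0 to 30 between sexes. In TG they went from 0 to 16, 2 to 20 and 33 to 54 (24 shared) at the 3 times, 0 to 19 for sex, 8 to 57 between times and 1 to 14 between sexes. Between ganglia the LPS effect went from 0 to 14, 0 to 12 and 2 to 81 (1 shared). For tRFs, 0 became 1 in SCG at 24 h, 1 for sex and 9 between sexes, in TG 13 at 24 h, 2 at 7 d, 7 for sex, 2 between times and 3 between sexes, and between ganglia 2 at 4 h and 12 at 24 h.

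With the DESeq2 test the miRNA calls in SCG went from 0 to 1, 2 to 7 and 3 to 40 (all 3 shared) at the 3 times and 5 to 25 for sex (5 shared). In TG they went from 0 to 2 at 4 h, 33 to 54 at 7 d (33 shared), 8 to 20 between times and 1 to 15 between sexes, and between ganglia from 0 to 3 at 24 h and 2 to 65 at 7 d. For tRFs 0 became 6 for sex in SCG, and 3 at 7 d and 2 for sex in TG. DESeq2 size factors moved the count between ganglia at 7 d from 2 to 12, and leaving out the sex term that of SCG at 7 d from 3 to 7. With only the 8 libraries of a time, fewer samples set the spread: SCG gave 2, 5 and 0 (main 0, 2 and 3) and TG 1 at 24 h, miR-146a-5p and neither of the main 2, and 1 at 7 d, miR-155-5p (main 33).

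Of the lists and comparisons tested for miRNAs 3 passed with an estimated correlation, 28 with a preset correlation of 0.01 and 21 with fry (2 shared). Of the tRF families 5, 50 and 11 passed (5 shared each).

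Without SCG 7 d LPS replicate 2 the calls went from 0 to 3 at 4 h, 2 to 6 at 24 h and 5 to 32 for sex in SCG, and from 2 to 18 between ganglia at 7 d. Without TG 7 d saline replicates 1, 2 and 4, where the lone saline library is assumed to vary like the other groups, 33 became 0 at 7 d, 8 became 0 between times, and between ganglia 2 became 0, as without both sets (0). Several log2 fold changes of called miRNAs in TG at 7 d then reversed: miR-124-3p to 0.15, miR-598-3p to 0.14, miR-128-3p to 0.13, miR-369-5p to 0.0146, miR-10a-5p to 0.0295 and miR-212-5p to 0.38. MiR-132-3p, lower but not called with all libraries, also changed sign, to 0.62. Against the saline libraries of 4 h and 24 h the calls at 7 d went from 3 to 29 in SCG and 33 to 1 in TG, where reversals were miR-486b-3p to -0.14, miR-344-3p to 0.0101, miR-124-3p to 0.15, miR-128-3p to 0.0302, miR-369-5p to 0.0713, miR-495-3p to 0.0509 and miR-212-5p to 0.20.

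Leaving out 1 library at a time moved the miRNA counts between these limits, with the library that gave them. In SCG they were 0 and 2 (LPS replicate 4; 1 without any saline library) at 4 h, 2 and 3 (LPS replicate 2) at 24 h, and 3 and 32 (LPS replicate 1; 29 and 13 without replicate 3 or 4) at 7 d, with 0 and 223 (7 d LPS replicate 1) between sexes. In TG they were 0 and 1 (LPS replicate 3) at 4 h, 1 (saline replicate 3 or LPS replicate 4) and 3 (LPS replicate 2) at 24 h, and 18 (LPS replicate 4; 19 without saline replicate 2) and 88 (saline replicate 3) at 7 d. Between times in TG they were 0 and 34 (7 d saline replicate 3), and between sexes 1 and 19 (7 d saline replicate 3). The LPS effect between ganglia gave 0 and 3 (SCG saline replicate 2) at 24 h and 0 and 62 (SCG 7 d LPS replicate 1 or 3) at 7 d. For tRFs they were 0 and 2 between sexes in SCG (4 h saline replicate 2), 0 and 1 in TG (7 d LPS replicate 3), and 0 and 5 at 7 d in TG (saline replicate 3).

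For single miRNAs, tRFs and lists the direction and side of the threshold held in 153 cases with DESeq2 size factors (1 no longer called), 143 with the DESeq2 test (11 newly called) and 125 without a low-count filter (17 newly called, 12 no longer). They held in 108 without a sex term (2 newly called), 64 with only 8 libraries (5 newly called, 29 no longer) and 36 with library size alone. Without TG 7 d saline replicates 1, 2 and 4, 72 held, 31 were no longer called and 6 reversed, and against the saline libraries of 4 h and 24 h 21 held, 2 were newly called, 18 no longer and 7 reversed. Without SCG 7 d LPS replicate 2, 42 held and 4 were newly called, and without both sets 2 were no longer called. When 1 library was left out, the comparison of ganglia apart, 888 held, 14 were newly called and 162 no longer. Libraries had a median of 204269 tRF and 3536934 miRNA counts, and the spread between replicates (biological coefficient of variation) was 0.58 in SCG and 0.408 in TG for tRFs and 0.448 and 0.27 for miRNAs. Simulated 2-fold changes were recovered for 8.96% of tRFs in SCG and 22.4% in TG, and which of depth and spread limits them was not tested. No paired analysis was possible because the labels do not say which SCG and TG libraries share a mouse.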

Other observations

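The tests in this part were all chosen after the results were seen, apart from the comparisons whose calls are repeated here. SCG 4 h saline replicate 1 had miRNAs of epithelium and muscle above every other SCG library except SCG 7 d LPS replicate 2 for some: miR-203-3p was 10553 CPM, miR-205-5p 631 CPM and miR-200b-3p 904 CPM, where the medians of 20 other SCG libraries were 306, 0.359 and 11.5 CPM. The muscle miR-1a-3p was 92427 CPM and miR-133a-3p 1586 CPM in it, against medians of 541 and 8.16 CPM.

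A hypothesis was that more resting leukocytes in the ganglia raised miR-155-5p and miR-21a-5p at 24 h. The 9 tested members of the leukocyte list should then rise as much, if ganglion cells hold little of them. In SCG without 7 d LPS replicate 2 their median log2 fold change was 0.76 (SD 0.66; highest 1.52), below the 3.08 of miR-155-5p and the 2.15 of miR-21a-5p, and in TG it was -0.00321 (SD 0.37), below 1.93 and 1.28. On that condition, which was not tested, more resting leukocytes as the whole cause are argued against by these values. The list mixes leukocyte kinds, so its median does not address the entry of a single kind. Leukocytes already activated by LPS, and resident cells of the ganglion, may have raised both miRNAs and were not tested.

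A second hypothesis was that miR-146a-5p rises later than miR-155-5p. Its LPS effect at 7 d lay above that at 4 h by a log2 of 1.89 ± 0.44 in SCG without 7 d LPS replicate 2 (SE; adjusted p = 0.0035, edgeR, Benjamini-Hochberg over 16 tests) and 1.41 ± 0.28 in TG (adjusted p = 0.000873), while for miR-155-5p the same difference was 0.01 ± 0.38 and -0.03 ± 0.54. With that library in, the log2 fold changes in SCG at 4 h and 7 d were 0.21 and 2.22 for miR-146a-5p and 1.73 and 2.28 for miR-155-5p. At 24 h, in SCG again without that library, the effect on miR-146a-5p lay above that at 4 h by 1.08 in SCG (adjusted p = 0.0417) and 0.79 in TG (adjusted p = 0.0211). For miR-155-5p that difference was 1.36 in SCG (adjusted p = 0.00615) and 0.43 ± 0.52 in TG (adjusted p = 0.546), and for miR-21a-5p 1.13 in SCG (adjusted p = 0.00615) and 0.94 in TG (adjusted p = 0.00415). The values may reflect a slower rise of miR-146a-5p, but whether the difference between the miRNAs itself holds was not tested. In TG the 7 d comparison includes saline libraries in doubt. Without replicates 1, 2 and 4 of these the log2 fold change of miR-146a-5p at 7 d went from 1.45 to 1.21. Against the saline libraries of 4 h and 24 h it was 1.17 (adjusted p = 0.000321, edgeR).

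Other splits of the same libraries were counted for each comparison except the LPS effect between sexes, where each sex has 2 libraries per group. They test the number of calls and not single miRNAs. For miRNAs chance can be excluded between the ganglia (1 of 100 splits, 333 calls, highest other 178). At 24 h in SCG only the real split gave 2 calls (1 of 35, highest other 0 by edgeR). That is the smallest share 35 splits can give and was not adjusted over the comparisons, so chance is unlikely there but not excluded. For sex in SCG 1 of 100 splits gave as many (5 calls, highest other 1). The real labels have 2 libraries of each sex per group, while the splits were drawn over all 24 libraries. That count therefore does not settle chance. For the number of calls chance cannot be excluded at 7 d in SCG (3 of 35, 3 calls). The highest other split there, with 28, points to a structure of the samples. Nor can chance be excluded for the number of calls at 24 h in TG (2 of 35, 2 calls, highest other 2). The 3 miRNAs called at 7 d in SCG lay above every 7 d saline library in 4 of 4 LPS libraries, were called without LPS replicate 2 (adjusted p = 0.00145 each, edgeR) and against the saline libraries of 4 h and 24 h (adjusted p between 0.000129 and 0.000416), and were not called with only the 8 libraries (adjusted p between 0.126 and 0.523). MiR-21a-5p at 24 h in TG lay above every 24 h saline library in 4 of 4 and was called without each library in turn (adjusted p at most 0.00243, edgeR) but not with only the 8 libraries (adjusted p = 0.203). The 3 calls at 7 d in SCG became 32, 29 and 13 without LPS replicate 1, 3 or 4, and at 24 h in TG 1 was left without saline replicate 3 or LPS replicate 4. At 4 h edgeR called 0 in SCG and in TG (13 and 15 at unadjusted p under 0.05, DESeq2 1 and 2), with as many in 35 of 35 splits each (highest other 1 and 2). Leaving out SCG 4 h LPS replicate 4 gave 2 calls, any 1 of the SCG 4 h saline libraries 1, and TG 4 h LPS replicate 3 1. For sex in TG edgeR called 0 (24 at unadjusted p under 0.05, DESeq2 0), with as many in 100 of 100 splits (highest other 5).

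For tRFs chance can be excluded between the ganglia (1 of 100 splits; 174 calls, highest other 77). In the other comparisons with splits edgeR called 0, so 35 of 35 or 100 of 100 splits gave as many. In SCG at 4 h, 24 h and 7 d the highest other splits called 2, 0 and 1 (39, 26 and 27 at unadjusted p under 0.05 in the real one, DESeq2 0), and in TG 2, 31 and 1 (21, 45 and 38, DESeq2 0, 0 and 3). For sex they called 37 in SCG and 2 in TG (50 and 53, DESeq2 6 and 2), between times 51 and 22 (23 and 20, DESeq2 0), and between ganglia at 4 h, 24 h and 7 d 2, 54 and 1 (30, 35 and 29, DESeq2 0). The splits with 22 or more calls, where the real one had 0 by edgeR, point to a structure of the samples, and what it is was not tested. At 7 d in TG 5 tRFs were called without TG 7 d saline replicate 3.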
